A study of Sus scrofa with 4 samples.

How the data were processed

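RNA from the longissimus dorsi muscle, the long back muscle, of 4 pig breeds was sequenced, with 1 library per breed. The indigenous type comprised Diannan Small Ear (DSP, replicate 1) and Tibetan (TP, replicate 2) pigs, and the introduced type comprised Landrace (LL, replicate 1) and Yorkshire (YY, replicate 2) pigs. The labels do not state how many animals stand behind a library, nor their sex, age or feeding. Reads were aligned with TopHat per the submitters' processing notes; its version, the genome build, the annotation version, the program that computed the expression values and the test behind the p-values are not given in the sources used here.

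The expression values were the FPKM of each breed, as deposited by the authors, and no read counts or depths were available, so no counting error was computed and the worth of 1 read is unknown. The deposited pooled FPKM of a type equalled the mean of its 2 breeds within 0.1% for all 17444 genes above 0 in the indigenous type and all 17404 in the introduced type. The deposited ratio, or fold change, divided the indigenous by the introduced pooled value. The authors' p-value, given with a false discovery rate, was within 10% of Fisher's exact test run on the pooled FPKM rounded up and taken as counts for 7599 of 7599 genes compared. That test reads no spread between breeds, so these values are quoted only as the authors' deposited table. The other deposited sheets, with 17444 and 17404 genes, held 0 cells that differed from the first sheet and were used only for this check.

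The table held 18208 genes. Of these, 12322 carried a name in the file, 2187 were named by their gene ID from reference tables for assembly Sscrofa11.1, 40 by a synonym, and 4248 kept an ID only. Only names were taken from those tables, in which 10612 of the IDs were found, and positions are the deposited ones. In all, 2253 genes shared their locus with another entry. Where a symbol had several entries, the one with the highest mean was used.

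The types were compared with limma 3.58.1 (trended prior variance) in R 4.3.3 on log2(FPKM + 1), with breeds as the replicates of a type. Genes entered with a mean of at least 1 FPKM, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. DSP was compared with TP, and LL with YY, without a test, as the difference of log2(FPKM + 1) and the count of genes at or past a 2-fold difference on that scale among genes with a mean of at least 1 FPKM over both values. All differences below are on the log2(FPKM + 1) scale, so that small values are drawn toward 0. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps.

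The 25 gene lists covered fatty acid and triglyceride synthesis, adipocyte markers, lipolysis and lipid droplets, fatty acid uptake and oxidation, slow fibre genes, fast fibre genes, embryonic and regenerating fibre genes, myogenic factors and growth axis, glycolysis and glycogen, oxidative phosphorylation, mitochondrially encoded genes, muscle protein breakdown, cytosolic ribosomal proteins, extracellular matrix and fibroblasts, endothelial and pericyte markers, smooth muscle markers, macrophage and leukocyte markers, red blood cell genes, Schwann cell and nerve markers, immediate early and heat shock genes, interferon and MHC class I genes, MHC class II genes, circadian clock genes, hypoxia and angiogenesis, and Y-linked genes and XIST. The 22 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. A list's median difference was also placed among 10000 random lists of the same size matched on mean expression in 20 bins, and the share of random medians under it is its percentile.

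Genes were named by a rule. For the types it took the 10 genes in each direction with the largest change among those passing, filled with the smallest unadjusted p. For a pair of breeds it took the 8 largest differences in each direction among genes with a mean of at least 5 FPKM. From each list it took the 2 most abundant members and the 2 with the largest difference. At most 2 genes with an ID only were named per direction. The groups, tests, lists, the naming rule and the alternatives were fixed before the data were examined, except for the alternatives named as later ones and the other splits of the libraries.

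The alternatives were a pseudocount of 0.1 or 5, no filter or a filter of 5 FPKM, rescaling to a common median ratio, rescaling to a common sum without the 50 most abundant genes, leaving out each library, limma without a trend or with a robust prior, a count of genes with both libraries of a type at least 2-fold past both of the other, and summing the entries of a symbol. Chosen after the data were seen were the library pair (DSP with LL, TP with YY) as a term, the loci of at least 300 bp without small RNA names, their combination, and list medians without each library.

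The steps were tested on simulated data with 11652 genes, in 40 simulations of 200 changed genes each, which made 2000 changed genes per size in all. With noise drawn from each gene's own moderated variance, limma called 0.45% of 2-fold, 6.5% of 4-fold, 42.8% of 8-fold and 76.8% of 16-fold changes, with a mean of 17.4% false calls. With noise drawn from limma's fitted prior it called 0%, 0.05%, 0.65% and 2.6%, with a mean of 7.58% false calls. In that mean a simulation without calls counted as 0, and 11 of all 77 calls were false. The changed genes were drawn from the more abundant genes only. The ratio of fitted to true change was 1 throughout. A shifted list of 20 genes was called by camera in 40 of 40 simulations and a random one in 1 of 40, and the matched-list percentile put 20 of 20 shifted lists in the upper tail and 0 of 20 unshifted lists in either tail. The simulated noise was independent between genes, so these counts do not cover lists whose members move together. In the data the estimated correlation was 0.749 for extracellular matrix and fibroblasts and 0.899 for cytosolic ribosomal proteins.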

Results

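Transcriptomes of the longissimus dorsi muscle were profiled in 4 pig breeds, with 1 library each, to find genes related to growth and fat deposition in muscle. DSP and TP stood for the indigenous Chinese type and LL and YY for the introduced type, so each type had 2 libraries and the spread within a type was that between breeds. The deposited FPKM summed to 1450760 in DSP, 880279 in TP, 1067280 in LL and 1226120 in YY, and sequencing depth was not given. Of the 18208 genes, 1673 were listed at 0 in DSP, 1687 in TP, 1355 in LL and 2422 in YY. Mitochondrially encoded genes took 24.0% of the FPKM in DSP, 33.2% in TP, 29.3% in LL and 25.4% in YY. Other loci shorter than 300 bp, many of them small RNAs, took 20.6% in DSP and 17.7% in LL, but 1.39% in TP and 5.55% in YY.

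The first comparison asked which genes differed between indigenous and introduced pigs. FASN and SCD, genes that build fatty acids, had their highest values in TP. FASN, the fatty acid synthase, averaged 30.0 ± 28.9 FPKM (SD, n = 2) against 2.76 ± 1.51 (SD, n = 2), and SCD, which makes monounsaturated fatty acids, averaged 72.5 ± 96.7 FPKM against 1.79 ± 0.851. The spread shows that 1 breed carried these means: FASN was 50.4 FPKM in TP and 9.52 in DSP, and SCD was 141 in TP and 4.08 in DSP. COL3A1, a fibrillar collagen of connective tissue, was lowest in YY, at 19.2 FPKM, against 154 in DSP, 277 in TP and 128 in LL. Limma passed 0 of 11652 genes after adjustment, with a smallest adjusted p of 0.263, and 130 genes had an unadjusted p under 0.05, of which 64 were higher and 66 lower in the indigenous type.

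The 18 tested members of the fatty acid and triglyceride synthesis list had a median difference of 0.52 between the types, with 11 members above 0, and the list ranked higher in the indigenous type (camera adjusted p = 0.000335). This call was lost with an estimated correlation (p = 0.101, adjusted p = 0.629). FASN differed by 2.69 (SE 0.80, limma adjusted p = 1) and SCD by 3.30 (SE 1.39, limma adjusted p = 1), and 3 members had an unadjusted p under 0.05. FASN and SCD passed with the library pair as a term, chosen after the data were seen. That fit gave genes of like expression the same variance, so it did not read a gene's own spread. SCD was 141 FPKM in TP, 4.08 in DSP, 2.39 in LL and 1.19 in YY, so its difference rested on TP. The list's median was 0.14 in DSP minus LL and 1.05 in TP minus YY, 0.28 without TP and 1.02 without DSP. Adipocyte markers had a median of 0.54, with 7 of 9 members above 0 and camera adjusted p = 0.0141, and p = 0.170 with an estimated correlation. PLIN1, which coats the fat droplet of adipocytes, was 11.5 FPKM in TP, 1.80 in DSP, 1.38 in LL and 1.01 in YY. The adipocyte median was 0.19 without TP and 1.15 without DSP, and under the median ratio scaling, which let in 1 more member, the call ended with adjusted p = 0.137, where the alternatives ranged from 0.00808 to 0.629. The lipolysis and lipid droplets list had a median of −0.02 (camera adjusted p = 0.178). In it, PLIN2, a droplet coat protein of muscle and other tissues, was 32.0 FPKM in DSP, 5.84 in TP, 71.3 in LL and 50.9 in YY (limma adjusted p = 1).

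**Figure D1:**
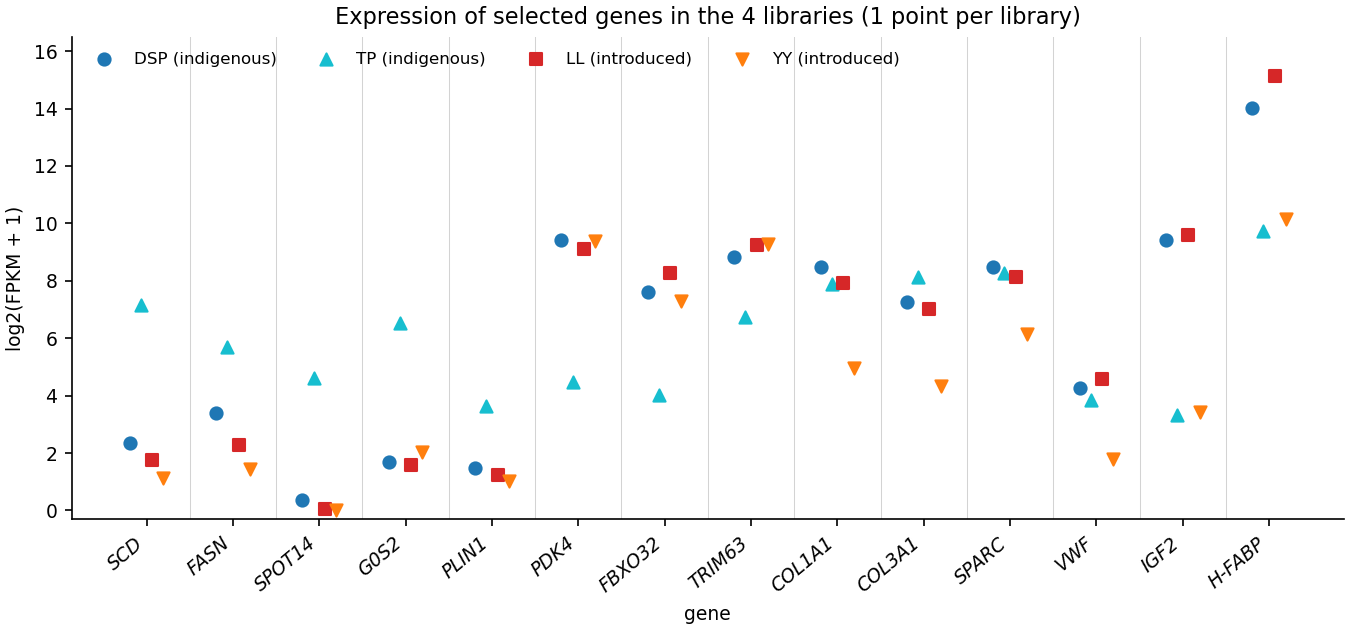
Values of selected lipid, protein breakdown, matrix and growth genes on the log2(FPKM + 1) scale, with 1 point per library and breed. SCD stands at 141 FPKM in TP and at 4.08 or less in the other 3 libraries, and COL3A1 stands at 19.2 FPKM in YY and at 128 or more in the others.

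The genes of fatty acid uptake and oxidation had a median of −0.27, with 19 of 25 members under 0 and camera adjusted p = 0.0476, and p = 0.290 with an estimated correlation. PDK4, a kinase that spares glucose when fat is burned, was 21.4 FPKM in TP against 692 in DSP, 546 in LL and 665 in YY. Without TP the list's median was 0.01, so its direction rested on that library, and it was −0.47 without DSP. The muscle protein breakdown list had a median of −0.62, with 17 of 20 members under 0 and camera adjusted p = 0.000820, and p = 0.314 with an estimated correlation. Its median was −0.11 without TP, −0.33 without YY and −1.08 without DSP. FBXO32 and TRIM63, muscle ubiquitin ligases that mark proteins for degradation, were 15.2 and 105 FPKM in TP, against at least 158 and 457 FPKM in each other library.

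Genes of cells and tissue around the fibres also differed by list. The extracellular matrix and fibroblasts list had a median of 1.11, with 21 of 24 members above 0 and camera adjusted p = 1.29e-10, and p = 0.215 with an estimated correlation. Its median was −0.16 in DSP minus LL and 2.33 in TP minus YY, and it moved to 0.28 without YY, 0.74 without TP and 1.79 without LL. COL15A1, a collagen of basement membranes, averaged 43.7 ± 9.70 FPKM against 12.7 ± 13.6 (limma adjusted p = 1). It passed with the library pair as a term, a fit that did not read its own spread. SPARC, which binds collagen, was 356, 308 and 282 FPKM in DSP, TP and LL and 69.0 in YY. Endothelial and pericyte markers had a median of 0.62, with 12 of 13 members above 0 and camera adjusted p = 0.000312, and p = 0.284 with an estimated correlation. Their median was 0.28 without TP, 0.29 without YY and 1.06 without LL. MHC class II genes, which present antigen, had a median of 0.88 with 5 of 5 members above 0 (camera adjusted p = 0.00380), and p = 0.181 with an estimated correlation. That median was 0.03 without TP and 1.68 without DSP. Oxidative phosphorylation genes had a median of 0.32 with 47 of 50 members above 0 (camera adjusted p = 0.0141), and p = 0.622 with an estimated correlation. Their direction turned without LL, to −0.44, and the median was 0.18 without TP, 0.52 without DSP and 1.07 without YY.

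The remaining lists did not pass with camera at the preset correlation. Median differences were −0.42 for slow fibre genes, 0.34 for fast fibre genes, 0.32 for embryonic and regenerating fibre genes, −0.04 for myogenic factors and growth axis, 0.30 for glycolysis and glycogen, 0.54 for mitochondrially encoded genes and −0.25 for cytosolic ribosomal proteins. They were 0.44 for smooth muscle markers, 0.35 for macrophage and leukocyte markers, 0.00 for immediate early and heat shock genes, −0.13 for interferon and MHC class I genes, 0.00 for circadian clock genes and 0.40 for hypoxia and angiogenesis. Lists with 3 members each were not tested, and had medians of 1.19 for red blood cell genes, 0.38 for Schwann cell and nerve markers and 0.72 for Y-linked genes. In each of the 25 lists, 0 members passed when adjusted over the list alone and 0 passed over all genes tested. With an estimated correlation 0 of the 22 lists tested passed, the smallest adjusted p being 0.629.

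**Figure D2:**
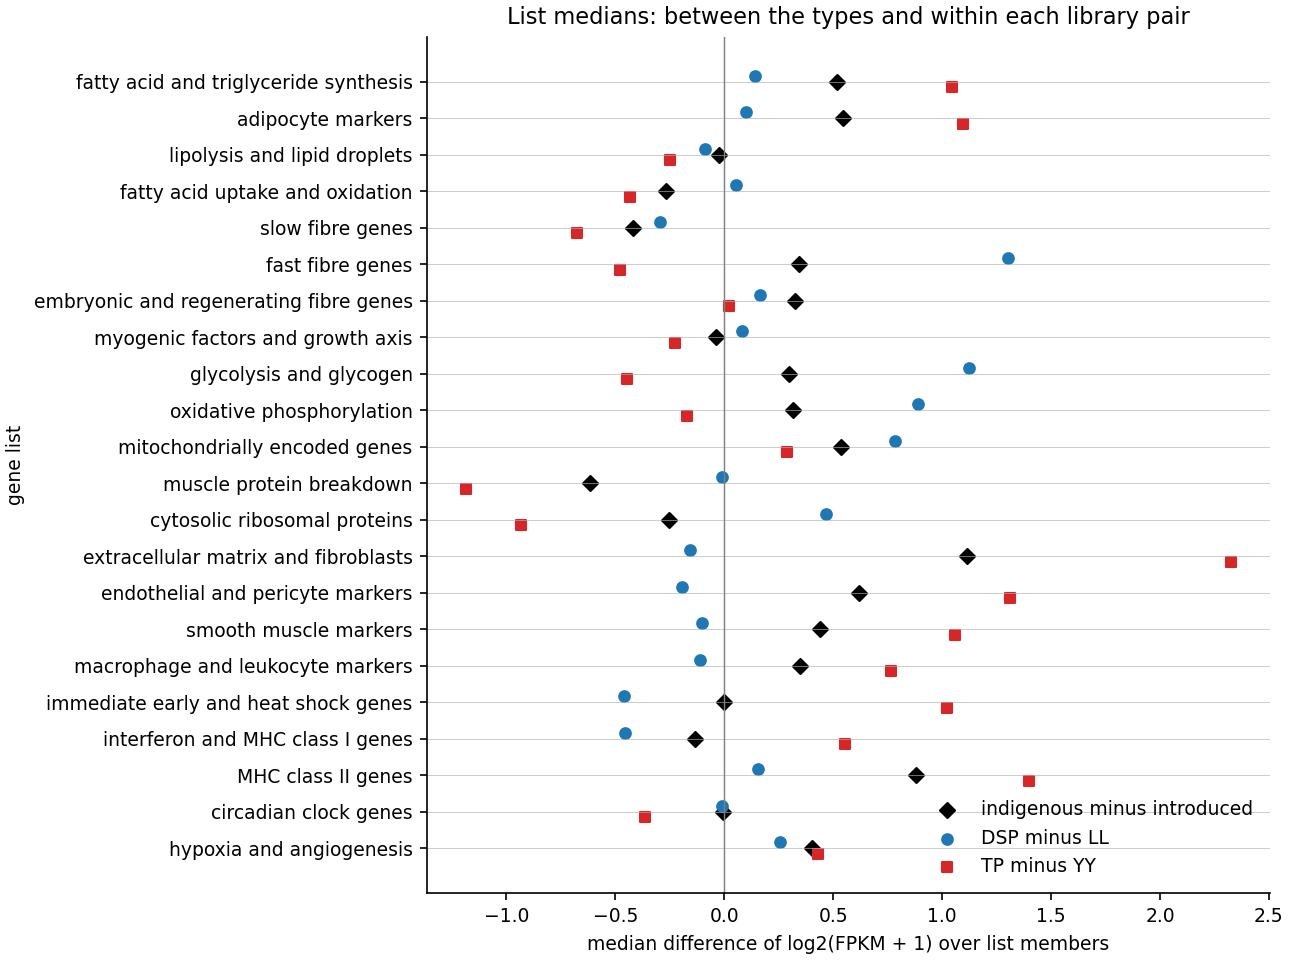
Median difference of log2(FPKM + 1) over the tested members of each gene list, between the types and within DSP minus LL and TP minus YY. The matrix list lies at 2.33 in TP minus YY and at −0.16 in DSP minus LL, and the fatty acid synthesis list at 1.05 and 0.14.

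With limma on the 2 types alone, none of the individual genes named next passed the adjusted threshold over all genes tested. With the library pair as a term, chosen after the data were seen and fitted on 1 residual degree of freedom, all of them but HR and CHRDL2 passed. ABHD16A also passed at loci of at least 300 bp, SNORA20 and SNORD22 passed without YY, and the 2 genes with an ID only passed in both and with a pseudocount of 0.1. The smallest p-values included ABHD16A, a lipid hydrolase read from an entry of 2128 bp (difference 8.77, SE 1.10, limma adjusted p = 0.387). That entry had 13630 FPKM in DSP, 1896 in TP, 7.71 in LL and 14.5 in YY, and whether it stands for the whole gene was not tested. APLN, which encodes the peptide apelin, was 5.94 FPKM in DSP and 6.42 in TP and listed at 0 in both introduced libraries (adjusted p = 0.435). STAC, which encodes an adaptor of calcium channels, averaged 14.1 ± 3.82 against 2.87 ± 1.48 FPKM. CENPU, SNORD17, an entry of 137 bp for MRC2, HR and CHRDL2 were other higher genes besides FASN, with differences between 1.55 and 4.95. Among the lower genes, the transcription factor IRX3 averaged 1.97 ± 1.78 FPKM against 13.7 ± 1.02, TTC9 averaged 5.88 ± 1.91 against 31.0 ± 6.09, and ZFAND2A, a stress-induced gene, averaged 4.94 ± 1.44 against 52.4 ± 42.1. CXCL10, an interferon-induced chemokine, was 1.24 FPKM in DSP, 3.35 in TP, 8.11 in LL and 24.6 in YY, with a difference of −2.29. The unnamed genes ENSSSCG00000026870 and ENSSSCG00000030266 were listed at 0 in both indigenous libraries and had 3436 and 539 FPKM in LL and 419 and 64.1 in YY. SNORA20, SNORD22, ENV and an entry of 166 bp for CDH2 completed the lower genes, with differences between −6.79 and −1.98.

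The authors' deposited table lists 605 genes with a false discovery rate under 0.05, of which 197 were higher and 408 lower in the indigenous type. Among these 605, 48 had an unadjusted limma p under 0.05 and 0 an adjusted one, and in 168 (27.8%) the types did not overlap, where chance gives 33.3% and all genes tested gave 18.6%. FASN and SCD were among them per the authors' deposited table, while 283 of the 605 had opposite signs in DSP minus LL and TP minus YY and 266 had the same sign. Their median expression was 193 FPKM, against 7.58 for all genes tested.

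The libraries paired across the types. The first principal component held 58.2% of the variance and separated DSP and LL from TP and YY. The correlation across genes, which are not independent replicates, was 0.893 for DSP with LL, 0.919 for TP with YY, 0.834 for DSP with TP and 0.803 for LL with YY. Differences between DSP and TP ran with those between LL and YY (r = 0.459 across genes), whereas DSP minus LL and TP minus YY had r = −0.03. Splitting the libraries as DSP and LL against TP and YY, limma passed 219 genes and 53.4% of genes did not overlap, against 0 genes and 18.6% for the types, where chance gives 33.3%. The remaining split, DSP and YY against TP and LL, passed 0 genes, with 104 at an unadjusted p under 0.05 and 27.4% not overlapping. These splits were not among the tests fixed beforehand. The counts describe a pairing seen in the same values and are no separate support for it. Without ties a gene does not overlap in only 1 of the 3 splits, so a high share in 1 split lowers the others. With the library pair as a term, added after this pairing was seen, 175 genes passed between the types, on 1 residual degree of freedom and with a prior that gave genes of like expression the same variance. FASN, SCD, ELOVL6, SPOT14, G0S2 and COL15A1 were among the 175, but 58 of the 175 were above 0 in 1 library alone, and 26 had opposite signs in DSP minus LL and TP minus YY. Without YY, 27 genes passed, with LL as the only introduced library and assumed to vary like the other type. All 27 were listed at 0 in both DSP and TP, and 16 were listed at 0 in YY too, so these calls rested on LL alone.

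**Figure D3:**
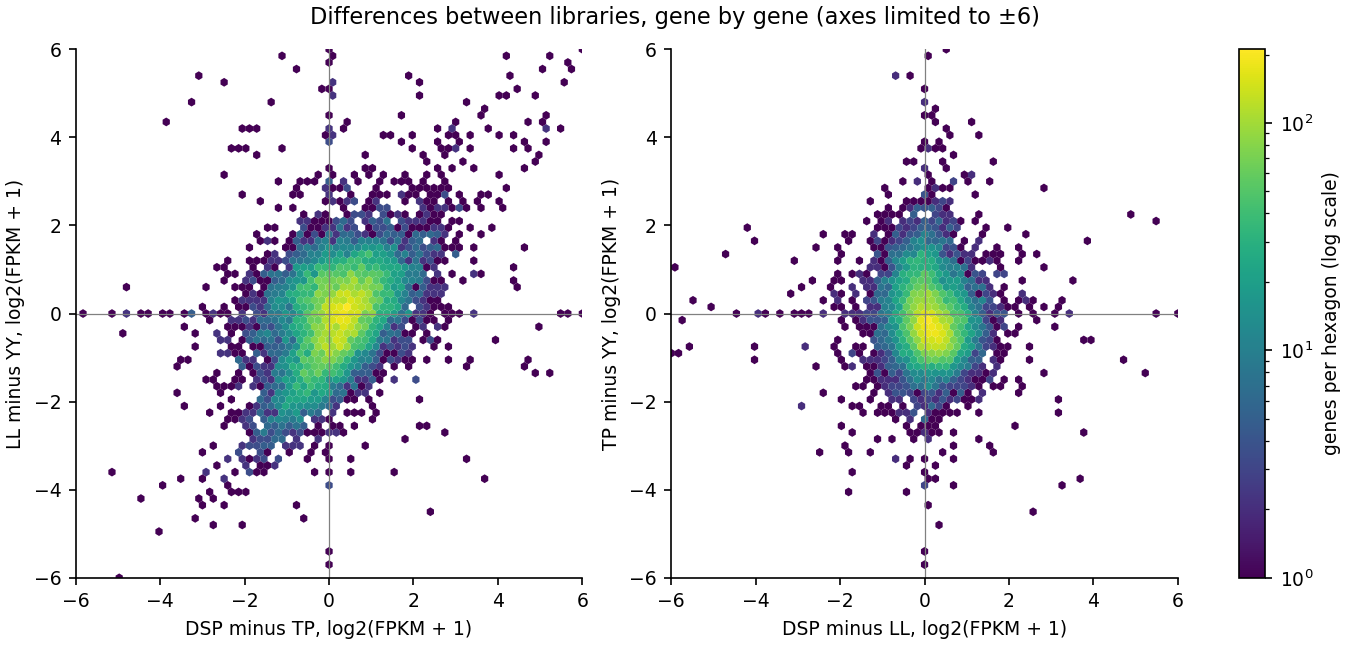
Hexagon counts of genes by their difference of log2(FPKM + 1), DSP minus TP against LL minus YY on the left and DSP minus LL against TP minus YY on the right, with axes limited to 6 units in either direction. The left cloud follows the diagonal (r = 0.459 across genes) and the right cloud does not (r = −0.03).

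The second comparison set the 2 indigenous breeds side by side. TP muscle had higher values of several genes for making fat. SCD was 141 FPKM in TP and 4.08 in DSP, and SPOT14, a thyroid hormone-responsive regulator of lipid synthesis, was 23.6 in TP and 0.297 in DSP. G0S2, an inhibitor of the lipase that empties fat droplets, was 92.0 FPKM in TP and 2.24 in DSP. DSP in turn had higher values of muscle protein breakdown genes, with FBXO32 at 195 FPKM against 15.2, and PDK4 was 692 FPKM in DSP against 21.4 in TP. With 1 library per breed there was no replicate check, and no p-values were computed for either pair of breeds.

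Of 11689 genes, 2729 differed at least 2-fold, 1822 higher in DSP and 907 higher in TP, so that 66.8% were higher in DSP. The median of all genes was 0.20 in DSP minus TP. It became −0.03 under the median ratio scaling, with 47.5% of the 2-fold genes higher in DSP, and −0.23 under the common sum, with 31.2%, so which breed had more genes higher depended on scaling. Fatty acid and triglyceride synthesis had a median of −0.55 in DSP minus TP (percentile 0.05 of matched random lists), with 12 of 18 members higher in TP, 8 of them at least 2-fold, and 4 at least 2-fold higher in DSP. Adipocyte markers had a median of −1.58 (percentile 0) and were higher in TP in 7 of 9 cases, with the complement factor CFD at 97.4 FPKM in TP and 20.8 in DSP and TUSC5 at 8.13 and 0.657. Muscle protein breakdown stood at 1.15 (percentile 99.9), with 17 of 20 members higher in DSP, among them FOXO3, a transcription factor of the atrophy programme, at 60.9 FPKM against 8.86. The fatty acid uptake and oxidation list was unremarkable as a whole, at 0.41 (percentile 70.7), although H-FABP, the heart-type fatty acid binding protein, was 16676 FPKM in DSP and 860 in TP. H-FABP followed the library pairs, as it was also higher in LL than in YY. Lipolysis and lipid droplets had a median of 0.05 (percentile 23.9), which turned to −0.22 under the median ratio scaling.

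Cell type markers were higher in TP. Smooth muscle markers had a median of −1.65 in DSP minus TP, macrophage and leukocyte markers −1.22 and extracellular matrix −0.72 (percentile 0 each), and endothelial and pericyte markers −0.71 (percentile 0.02). Members higher in TP numbered 6 of 7, 8 of 9, 18 of 25 and 11 of 13. TAGLN, an actin-binding protein of smooth muscle, was 89.3 FPKM in TP and 10.9 in DSP, and C1QA, a complement gene of macrophages, was 15.1 and 1.62. Collagen VI followed, with COL6A1 at 43.4 FPKM in TP and 10.1 in DSP, but COL1A1, read from an entry of 526 bp, was 234 in TP and 355 in DSP. MHC class II genes stood at −1.71 (percentile 0.01), with SLA-DQA1 at 55.6 FPKM in TP and 13.7 in DSP. Immediate early and heat shock genes stood at −1.22 (percentile 0), and the early-response transcription factors FOS and ATF3 were 641 and 394 FPKM in TP and 47.1 and 34.3 in DSP. Haemoglobin genes were also higher in TP, HBA at 204 FPKM against 36.7 and HBB at 321 against 117, and red blood cell genes had a median of −0.78 over 4 members.

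Ribosomal protein genes were higher in TP in 52 of 53 cases, with a median of −0.96 (percentile 0), and oxidative phosphorylation genes had a median of −0.34 (percentile 0.08), with 35 of 50 higher in TP. In the same library, 24 of 25 very long transcripts, a list made after the data were seen, were lower than the mean of the other 3 libraries (median −0.76, percentile 0). IGF2, a growth factor for muscle, was 682 FPKM in DSP and 9.03 in TP, and MYH3, the embryonic myosin, was 179 and 38.9. The IGF2 gap followed the library pairs, since IGF2 was also high in LL and low in YY. Breed cannot be told apart here from what the paired libraries share. The medians of myogenic factors and growth axis (0.57, percentile 92.7), embryonic and regenerating fibre genes (0.55, percentile 92.4), slow fibre genes (−0.06, percentile 26.1), glycolysis and glycogen (0.45, percentile 80.2) and circadian clock genes (0.36, percentile 70.5) lay inside the range of matched lists. So did fast fibre genes (0.24, percentile 51.8), whose median turned to −0.03 under the median ratio scaling, and mitochondrially encoded genes (−0.60, percentile 2.61). Interferon and MHC class I genes stood at −0.29 (percentile 0.48) and hypoxia and angiogenesis at −0.23 (percentile 2.21, and 2.77 with a pseudocount of 0.1). Schwann cell and nerve markers had a median of −0.54 over 4 members and Y-linked genes −0.81 over 3. The largest single differences were mostly small RNAs listed at 0 in 1 of the 2 breeds. Single entries of U6 and SNORA71 had 2877 and 2082 FPKM in DSP and were listed at 0 in TP, as were single entries of 5S_rRNA, snoU13 and SNORA31 and an entry of 120 bp for RYR3. Some other entries of U6 and 1 of SNORA31 were listed at 0 in DSP and had values in TP, and with the entries of a symbol summed the difference went from 11.49 to 3.98 for U6 and from 10.77 to 5.69 for SNORA31. In the other direction, the unnamed ENSSSCG00000018076 had 36632 FPKM in TP and was listed at 0 in DSP.

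The third comparison set the 2 introduced breeds side by side. LL muscle had higher values of connective tissue genes than YY. COL1A1, a fibrillar collagen read from its entry of 526 bp, was 240 FPKM in LL and 30.0 in YY, LOX, which cross-links collagen, was 12.2 and 0.691, and VWF, a clotting factor of endothelium, was 22.7 and 2.44. YY had higher values of ribosomal protein and oxidative phosphorylation genes, with RPS16 at 1122 FPKM against 66.0 and the cytochrome oxidase subunit COX6A2 at 144 against 24.1. IGF2 was 781 FPKM in LL and 9.66 in YY, so it was high in DSP and LL and low in TP and YY, as the libraries paired.

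Of 11412 genes, 3443 differed at least 2-fold, 1533 higher in LL and 1910 higher in YY, and the median of all genes was 0.00. The share higher in LL was 44.5%, with 50% under the median ratio scaling and 67.3% under the common sum, which moved the median to 0.33, so which breed had more genes higher depended on scaling. The extracellular matrix and fibroblasts list had a median of 1.92 in LL minus YY (percentile 100) with 24 of 24 members higher in LL, and endothelial and pericyte markers had 0.85 (percentile 99.7). Smooth muscle markers stood at −0.27 (percentile 30.3) and macrophage and leukocyte markers at −0.28 (percentile 4.46). Interferon and MHC class I genes stood at 0.53 (percentile 98.9) with 13 of 23 members higher in LL, and with a pseudocount of 0.1 the percentile was 95.3, inside the range of matched lists. The antiviral genes RSAD2 and MX2 were 36.8 and 12.2 FPKM in LL and 0.563 and 0.432 in YY, but CXCL10 was 8.11 in LL and 24.6 in YY. Myogenic factors and growth axis stood at 0.66 (percentile 99.95) with 15 of 24 members higher in LL, although EIF4EBP1, a repressor of translation, was 44.8 FPKM in LL and 191 in YY.

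All but 1 of the 53 ribosomal protein genes were higher in YY, with a median of −2.32 in LL minus YY, and oxidative phosphorylation had −1.61 (percentile 0 each). In YY, 23 of 25 very long transcripts were lower than the mean of the other 3 libraries (median −0.55, percentile 0.01). Fast fibre genes had a median of −1.71 with 9 of 9 members higher in YY, yet this lay inside the range of matched lists (percentile 6.53), as did glycolysis and glycogen at −1.17 (percentile 11.5), mitochondrially encoded genes at −1.19 (percentile 30.2) and slow fibre genes at −0.36 (percentile 78.3). MYL1, a fast myosin light chain, was 19892 FPKM in YY and 2635 in LL. HSPB1, a small heat shock protein, was 6058 FPKM in YY and 733 in LL, while immediate early and heat shock genes together stood at −0.27 (percentile 63.3). Lipid lists did not stand out. Fatty acid and triglyceride synthesis stood at 0.39 (percentile 93.1), adipocyte markers at 0.06 (percentile 50.1), lipolysis and lipid droplets at −0.20 (percentile 34.1) and fatty acid uptake and oxidation at −0.27 (percentile 64.9). H-FABP was 36228 FPKM in LL and 1145 in YY, and like IGF2 it followed the library pairs. Muscle protein breakdown stood at −0.20 (percentile 88.8), embryonic and regenerating fibre genes at 0.37 (percentile 81.5), circadian clock genes at −0.23 (percentile 23.0) and hypoxia and angiogenesis at −0.20 (percentile 31.3). Lists too small for a percentile had medians of 1.13 for red blood cell genes, −0.90 for Schwann cell and nerve markers, −0.30 for MHC class II genes and 2.41 for Y-linked genes. The largest single differences were again mostly small RNAs, with SNORD88, U5 and SNORA40 at 5973, 1129 and 844 FPKM in LL and listed at 0 in YY. An entry of 79 bp for TRAPPC9 had 11661 FPKM in LL and 13.9 in YY, and IGLC, an immunoglobulin light chain, had 63.9 FPKM in YY and 1.63 in LL.

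The Y-linked genes, a check on the sex of the animals, which the labels do not state, were above 1 FPKM in DSP, TP and LL. USP9Y was 3.72, 9.89 and 4.65 FPKM in these libraries and 0.0218 in YY, ZFY was 1.92, 4.12 and 4.42 and 0.0205 in YY, and UTY was 1.90, 2.61 and 3.50 and listed at 0 in YY. Every difference that involves YY thus also sets a library near 0 in these genes against libraries above 1 FPKM.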

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

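The library pair as a term, the loci of at least 300 bp, their combination and the list medians without a library were chosen after the data were seen. Between the types, 0 genes passed under 7 of the alternatives besides leaving out a library. The exceptions were 3 genes with a pseudocount of 0.1 (among them ENSSSCG00000026870 and ENSSSCG00000030266), 4 at loci of at least 300 bp (among them the same genes and ABHD16A), 175 with the library pair as a term and 82 with both, and without a test 53 genes had both libraries of a type 2-fold past the other. Leaving out a library gave 0 to 27. Genes at an unadjusted p under 0.05 numbered 359 without a filter, 71 at 5 FPKM and 366 without LL, against 130. For DSP against TP, a pseudocount of 5 gave 1447 genes (1036 higher in DSP, 411 in TP), the common sum 885 and 1951, and 5 FPKM left 580 higher in TP. For LL against YY, a pseudocount of 5 gave 1886 genes, 591 higher in LL, 5 FPKM left 859 higher in LL, and the common sum gave 2478 and 1205. Camera passed 7 lists under the median ratio scaling, 8 with a pseudocount of 0.1, 8 at loci of at least 300 bp and 0 with an estimated correlation, and was not run under the rest. Of the lists called by camera, medians turned for oxidative phosphorylation (−0.437 without LL, range −0.437 to 1.07) and fatty acid uptake and oxidation (0.0103 without TP, range −0.470 to 0.0103). Of all 25 list medians between the types, the sign changed in 3 without DSP, 4 without TP, 7 without LL, 4 without YY and 4 under the median ratio scaling. Under the median ratio scaling, 5 of 95 named genes changed sign in DSP against TP, 0 of 105 between the types and 0 of 100 in LL against YY. Summing the entries of a symbol moved single named differences by up to 7.51 in DSP against TP and 9.28 in LL against YY, with 0 changes of sign. The cause of these shifts was not tested, except that dropping loci, libraries or low values leaves fewer values. With no read counts, what depth limits is unknown.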

Other observations

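The test of short loci, the test of PDK4, FBXO32 and TRIM63 against fibre genes, the comparison of cell type markers in YY, the test of sex, and the differences between DSP and LL and between TP and YY were chosen after the result was seen. Between DSP and LL, muscle of different types, 890 of 11615 genes (7.66%) differed at least 2-fold, against 1957 of 11333 (17.3%) between TP and YY. Fast fibre, glycolysis and oxidative phosphorylation genes had higher values in DSP than in LL. Fast fibre genes had a median of 1.30 in DSP minus LL with 9 of 9 members above 0 (percentile 99.98 of matched lists), glycolysis and glycogen 1.12 (percentile 100) and oxidative phosphorylation 0.89 (percentile 100), while slow fibre genes stood at −0.30 (percentile 0.095) and fatty acid uptake and oxidation at 0.05 (percentile 3.10). LDHA, the lactate dehydrogenase of fast muscle, was 6342 FPKM in DSP and 1883 in LL, and MYH1, a fast myosin, was 14097 and 5708. In each of 8 abundant fibre genes LL was the lowest library, while DSP was the highest only in MYH1 and ATP2A1. The fast fibre gene TNNC2 was 12938 FPKM in DSP, 13505 in TP, 6200 in LL and 24775 in YY. For these fibre genes the gap thus lay with low values in LL, not with values particular to DSP. Interferon and MHC class I genes were lower in DSP than in LL, with a median of −0.45 (percentile 0). Immediate early and heat shock genes were lower as well, at −0.46 (percentile 0) with 17 of 22 members below 0. Mitochondrially encoded genes stood at 0.78 (percentile 98.3) with 13 of 13 members higher in DSP.

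Between TP and YY, extracellular matrix genes had a median of 2.33 with 24 of 24 members higher in TP (percentile 100), and immediate early and heat shock genes 1.02 (percentile 100). The nuclear clock repressor NR1D1 was 71.4 FPKM in YY and between 12.2 and 22.0 in the other libraries. Hypoxia and angiogenesis genes had a median of 0.43 in TP minus YY (percentile 100), with 9 members above 0 and 8 below.

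The libraries paired as DSP with LL and TP with YY. Loci under 300 bp and small RNA names are argued against as the whole source of the pairing. In the 11462 of 11652 genes left without them, DSP minus TP still ran with LL minus YY (r = 0.4811 across genes, against 0.459 with them). This r differed with the span of the locus, at 0.667 for 300 to 1000 bp and 0.286 for 30000 to 100000 bp, so a part played by locus length stays open. Better recovery of long transcripts in DSP and LL may contribute: the mean of DSP and LL was above that of TP and YY in 25 of 25 very long transcripts, with a median of 1.03 at percentile 100 of matched random lists. Single libraries overlapped in NEB, RYR1, SYNE2 and XIRP2, which were lower in LL than in YY, and in UTRN, which was highest in TP. The difference between the pairs did not rise steadily with locus span, however. Its median was 2.54 for the 47 loci under 150 bp, −0.17 at 3000 to 10000 bp and 0.32 from 100000 bp up. A shared day, batch or handling of the paired samples is not recorded in the labels and stays open, as does a biological likeness of the breeds, which was not tested. An exchange of 2 labels between the types also stays open, was not tested, and would change what every difference between the types means.

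Several fat synthesis genes were high in the TP library. More adipocytes in the TP sample is a candidate explanation, since 6 adipocyte genes outside the fixed lists had a median of 1.049 in TP minus the mean of the other 3 libraries (percentile 99.96), with 5 above 0 and ACSM5 lowest in TP, at 11.1 FPKM. By the same measure, smooth muscle markers stood at 1.36, extracellular matrix at 1.13 and macrophage and leukocyte markers at 1.08 (percentile 100 each). The rise was thus not particular to adipocyte genes. The 6 genes were FABP5, LIPA, MMD, GPAT3, KCNIP2 and ACSM5, all above 0 in every other library. Whether they are read from adipocytes alone was not tested. KCNIP2, however, was under 1 FPKM outside TP, at 0.415 in DSP, 0.187 in LL and 0.870 in YY against 3.76 in TP. It thus reached the filter of a mean of 1 FPKM only through its TP value. Of the 6, FABP5, the most abundant, was 152 FPKM in TP and 49.8 to 78.3 in the others. The adipocyte list's most abundant genes, GPD1 and CFD, were 866 and 97.4 FPKM in TP and 1046 and 63.5 in YY, while ADIPOQ, FABP4 and LPL were not found by name. Over 8 abundant fibre genes, which added cells would dilute alike, the median was 0.16 in TP minus the mean of the other 3 libraries, with 5 above 0. Relative to it, PDK4, FBXO32 and TRIM63, picked because they were low in TP, had a median change of −3.871. More adipocytes is therefore argued against for these 3 genes. A fed state of the animal or animals behind TP cannot be told apart for these genes. The median of 16 fasting and glucocorticoid response genes was −0.4114 in TP, short of the bound set for it and at percentile 26.1. Even so, 14 of the 16 were lower there, 6 of them at least 2-fold, and 0 were at least 2-fold higher. Breed stays open and untested.

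Extracellular matrix genes were low in the YY library, with a median of −1.72 against the mean of the other libraries and 20 of 24 members at least 2-fold lower. Smooth muscle markers (−0.16, 3 of 6 members lower) and macrophage and leukocyte markers (−0.10, 6 of 9 lower) lay at least 1.556 above the matrix median, so these markers did not fall alike with the matrix. Whether there were fewer cells of every type other than fibres stays open. The bound on this gap was set after the medians were known, and the first form of the test, the marker medians alone, had left the question open. The matrix was not alone, as endothelial and pericyte markers stood at −0.84 with 13 of 13 members lower and red blood cell genes at −1.48 with 3 of 3, so fewer vessels and less blood with the matrix stay open. Poorer recovery of long transcripts in YY is argued against as the whole source, because very long transcripts lay 1.168 above the matrix median. The sex of the animal or animals behind YY cannot be told apart from their breed. YY was the only library with all Y-linked genes near 0 (at most 0.02175 FPKM), and sex, breed and library coincide in it. Less matrix synthesis in YY was not tested.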
